A study of Arabidopsis thaliana with 6 samples.

How the data were processed

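RNA was sequenced from cells collected as male meiocytes of Arabidopsis thaliana, pressed out of anthers of stages 4 to 7, from the strain Ler and from knu-2, with 3 libraries per genotype. Per the labels' protocols, polyadenylated RNA was captured with oligo-T beads and fragmented, and cDNA was made with random hexamers. No step that marks the strand is named there. The aligner, the counting tool, their versions, the genome build and the strand setting are not given in the sources used here. The deposited files hold 1 whole-number count per gene and library, with the length of each gene beside it in base pairs as another value, and the authors deposited these counts without normalization, as judged from the values. The lengths were used only to compare the gene models with the reference annotation. Each library was a separate file, so no column of other samples was used. Groups and replicate numbers came from the labels. The labels call the libraries biological replicates and do not say whether they came from separate plants, so the p-values measure the spread between these collections.

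Each file holds 27655 genes, of which 27445 were found by identifier in the TAIR10.1 reference annotation and the others are organelle genes. Of those found, 27272 (99.4%) had exactly the length of the merged exons in that annotation. Coordinates are those of TAIR10.1. Library totals were between 18070435 and 27995200 counts, so that a gene with no count in a library lay below 0.119 to 0.166 scaled CPM, taking 3 counts as the limit that a count of 0 allows. These limits cover counting error only. Pairs of libraries of 1 genotype differed by far more than sampling noise, with a chi-square of at least 20.3 per degree of freedom over genes, so none was a copy of another.

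The tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with edgeR's filterByExpr, which left 18422. The 9233 genes left out held 0.0769% of all counts. Libraries were scaled with the TMM method, which gave factors of 0.870 to 0.914 for Ler and 1.06 to 1.21 for knu-2, and CPM values are scaled by them. A robust quasi-likelihood model with genotype as its only term was fitted to all 6 libraries (glmQLFit and glmQLFTest), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every p-value given for a single gene comes from this edgeR model unless another test is named. The standard error of a log2 fold change was taken from its test statistic. Where a genotype had no count in any library, the fold was computed against a floor of 3 counts over the 3 libraries of that genotype and is a lower bound.

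Gene lists were fixed before the data were examined: CDK inhibitors, G1 and G1/S regulators, DNA replication genes, G2/M genes, meiotic recombination and axis genes, genes of the meiotic divisions and exit, tapetum regulators and exine genes, early anther cell fate genes, floral organ and meristem genes, photosynthesis genes, pollen genes, wound and jasmonate response genes, and heat shock genes. The tapetum, early anther, floral organ, photosynthesis and pollen lists stood for cells other than meiocytes that the collections could hold. An entry was dropped when the reference gives its identifier another symbol (3 entries). The 13 lists were tested on voom values with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Camera compares a list with all other genes, whereas fry asks if the members move one way on balance. Families were found by fixed keywords in the reference descriptions and tested the same way when 10 or more members were measured, which left 14. They were ribosomal proteins, histones, kinesins, F-box, heat shock, lipid transfer, pectin-related, WRKY, expansin, AGAMOUS-like, cytochrome P450, peroxidase, ubiquitin-related and pentatricopeptide proteins. The genes named in the text were also set by a rule fixed then: KNU, KRP1 and KRP3, the 8 largest rises and 8 largest falls among called genes with an average of 5 CPM or more and no overlap between the genotypes, up to 4 members with the smallest p in each list, and up to 2 members of each family that passed. Other genes are said to be chosen after their values were seen. Genes around KNU were compared with all others by Fisher's exact test. Shares of each library were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1.

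The fits were tested on simulated data with the means and library sizes of these libraries and their common dispersion for every gene, in which 100 of 18422 genes were changed 2-fold and 100 were changed 4-fold. The edgeR model recovered 6% of the former and 84% of the latter, with 3 of its calls false. limma-voom recovered 6% and 84%, with 2 false calls, and DESeq2 recovered 15% and 90%, with 26 false calls. The alternatives were a replicate block, DESeq2 size factors in the edgeR fit, no scaling beyond library totals, the DESeq2 Wald test, limma-voom, no filter on low counts, a filter at an average of 5 CPM, leaving out each library in turn, stricter thresholds, and windows of 2 and 10 Mb around KNU. Reads shared by near-identical genes cannot be assigned from the counts, so values of ZYP1A and ZYP1B, of the LHCB1 and RBCS genes and of the tubulin genes are uncertain. Of the 71 genes named by the rule for single genes and lists, 21 overlap a gene on the other strand and 2 overlap one on the same strand, and their counts may hold reads of the neighbour.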

Results

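Transcripts of cells collected as male meiocytes, the cells of the anther that go through meiosis, were measured by RNA sequencing in 2 genotypes of Arabidopsis thaliana. Ler is the laboratory strain Landsberg erecta, and knu-2 carries a mutant allele of KNUCKLES (KNU), which encodes a zinc finger protein. Anthers of stages 4 to 7 were pressed open and the released cells were collected, with 3 libraries per genotype. No sort of the cells is named in the labels, so the collections could hold other anther cells. Library totals were 26150115, 27995200 and 19827980 counts for Ler replicates 1 to 3 and 18201902, 18070435 and 23199970 counts for knu-2 replicates 1 to 3. The first principal component of log2 CPM held 65.3% of the variance and separated the genotypes, and the second held 13.1%. Spearman correlations across genes were between 0.976 and 0.983 among Ler libraries, between 0.951 and 0.961 among knu-2 libraries, and between 0.804 and 0.890 across genotypes. Chloroplast genes took 0.0316 ± 0.00104% of the counts in Ler and 0.0422 ± 0.0211% in knu-2 (SD, n = 3 each, exact permutation p = 0.7). Mitochondrial genes took 0.0198 ± 0.00356% and 0.0512 ± 0.0441% (exact permutation p = 0.2), with the largest value, 0.102%, in knu-2 replicate 2.

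The title of the series names KRP1 and KRP3, which encode inhibitors of cyclin-dependent kinases, as genes directly repressed by KNU, and the first question was how these 3 genes differed in knu-2. KNU transcript fell from 76.8 ± 9.69 CPM in Ler to 8.63 ± 4.68 CPM in knu-2 (SD, n = 3 each), 8.94-fold lower, and every knu-2 library lay below every Ler library. KRP3 rose 2.78-fold, from 2.84 ± 1.301 to 7.89 ± 1.82 CPM. KRP1 stood at 3.36 ± 1.37 CPM in Ler and at 7.47 ± 2.80 CPM in knu-2, 2.23-fold higher, and did not pass the threshold over all genes. All 3 knu-2 libraries lay above all 3 Ler libraries for both KRP genes. In the edgeR model the log2 fold changes were -3.16 (SE 0.36, adjusted p = 0.000128) for KNU, 1.47 (SE 0.46, adjusted p = 0.0201) for KRP3 and 1.16 (SE 0.47, adjusted p = 0.0609) for KRP1. Adjusted over the list alone, which holds these 3 genes, the p-values were 3.6e-05, 0.0122 and 0.0303, so that KRP1 passed. The title names both KRP genes for the study that these libraries belong to, so the list is not independent evidence of their direction. In the same libraries the meiotic recombination list had a median log2 fold change of -2.50 and the tapetum list one of 1.37. A change in the mix of cells was not tested apart from the fall of KNU and the rises of the KRP genes. KNU (AT5G14010) is a gene with a single exon on chromosome 5, from 4522149 to 4522935 of TAIR10.1. KRP1 (AT2G23430) lies on chromosome 2, from 9976590 to 9978090, and KRP3 (AT5G48820) on chromosome 5, from 19792270 to 19794480. The KRP genes were measured from 32 to 227 counts per library, and whether either gene passed depended on single libraries. KRP3, called with all libraries, was not called without Ler replicate 1 (adjusted p = 0.0664) or without knu-2 replicate 1 (0.0579). KRP1 was called without knu-2 replicate 3 (log2 fold change 1.39, adjusted p = 0.0388), with no scaling beyond library totals (1.501, adjusted p = 0.0248) and with the filter at an average of 5 CPM (1.26, adjusted p = 0.0328), within a range of 0.0248 to 0.199 over all alternatives.

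**Figure D1:**
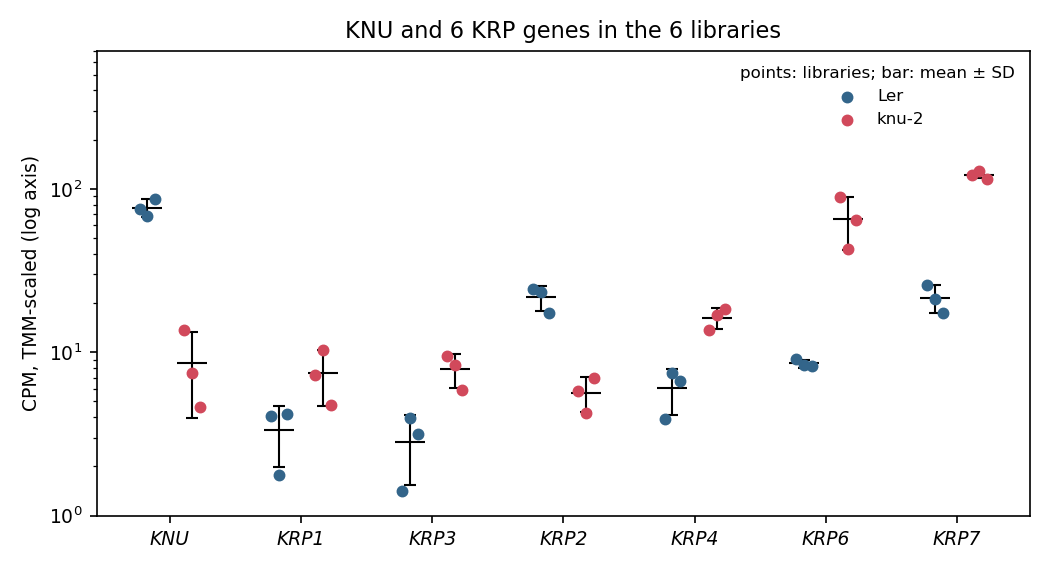
Levels of KNU and 6 KRP genes in CPM (log axis), 1 point per library, with the mean and SD of the 3 libraries of each genotype. KNU fell from a mean of 76.8 to 8.63 CPM and KRP2 from 21.7 to 5.67 CPM, whereas KRP6 rose from 8.54 to 65.6 CPM and KRP7 from 21.5 to 122 CPM.

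Across the transcriptome, 4355 genes were higher and 4501 were lower in knu-2, which is 48.1% of the 18422 genes tested. The largest rises were in genes with no count in any Ler library. AT2G16960, an ARM repeat protein, was at 27.8 ± 6.23 CPM in knu-2 (SD, n = 3) and at least 602-fold higher, the neighbours AT1G36920 and AT1G36922 were at least 573-fold and 533-fold higher, and AT2G36540 was at least 257-fold higher. AT1G05330 had 2 counts in Ler and 801 in knu-2, a ratio of 400 with an exact 95% counting interval of 110 to 3312. AT2G23970, the NAC transcription factor gene NAC003 and the phosphatase gene PEPC1 rose by 7.497 (SE 0.62), 6.86 (SE 0.62) and 6.49 (SE 0.84) on the log2 scale. The largest falls were in AT3G09490, a tetratricopeptide repeat protein (-6.68, SE 0.98), AT1G09740 (-5.58, SE 0.72), which overlaps AT1G09730 on the other strand, the pectin methylesterase gene PMEPCRF (-5.24, SE 0.92), which overlaps AT5G53360 on the other strand, and SDH1-2, which encodes a subunit of mitochondrial succinate dehydrogenase (-5.15, SE 0.85). AT3G18180 (-5.12, SE 1.13), AT1G65165 (-4.88, SE 1.57, adjusted p = 0.0471), which overlaps AT1G65160 on the same strand, AT2G34580 (-4.81, SE 1.22) and AT3G57440 (-4.80, SE 0.98) followed. All of these passed an adjusted p of 0.05 in edgeR, where 2905 genes rose and 3053 fell by 1 or more on the log2 scale. In 59.1% of the tested genes the 3 values of one genotype lay apart from the 3 of the other, where chance gives 10%. With no scaling beyond library totals, 6149 genes were higher and 3499 lower, so that 63.7% of the calls were higher against 49.2% with TMM, and the fold changes of all genes shifted by a median of 0.32 on the log2 scale. AT3G18180 lost its call without Ler replicate 2 or 3 (adjusted p = 0.0532 in each case), AT2G34580 without any 1 of the Ler replicates or knu-2 replicate 3 (0.0577 to 0.0928). AT1G65165 lost it without any 1 of the Ler replicates, knu-2 replicate 2 or knu-2 replicate 3 (0.0525 to 0.121), with DESeq2 size factors (0.0514), with DESeq2 (0.0658) and with no filter on low counts (0.0951). The log2 fold changes of AT1G05330 (7.75), AT2G23970 (8.49) and PEPC1 (9.27) moved by over 1.5 times on the linear scale without Ler replicate 2, as did NAC003 (7.78) without Ler replicate 1. The same held for AT3G18180 (-7.42), AT2G34580 (-6.46) and AT3G57440 (-6.34) without knu-2 replicate 1, AT2G34580 (-4.22) without knu-2 replicate 2, AT1G65165 (-4.20) without Ler replicate 3, and AT3G09490 (-6.06), PMEPCRF (-4.63) and AT1G65165 (-4.26) without knu-2 replicate 3. AT1G05330 without Ler replicate 3 and AT3G09490 and AT1G65165 without knu-2 replicate 1 had no count left in that genotype.

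Most genes of meiotic recombination and of the chromosome axis fell in knu-2. Of 38 measured, 32 were lower, 1 was higher and 5 were not called, with a median log2 fold change of -2.50, which is 5.64-fold lower. MND1, a cofactor of strand exchange, fell from 273 ± 37.8 to 32.7 ± 11.9 CPM (SD, n = 3 each). PRD1, which is needed for meiotic double-strand breaks, fell from 145 ± 11.1 to 17.0 ± 7.38 CPM. HEI10, a crossover factor, fell from 164 ± 29.3 to 41.1 ± 6.77 CPM and the nuclease gene MRE11 from 94.0 ± 4.46 to 35.4 ± 3.78 CPM. REC8, the meiotic cohesin gene and the 1 member that was higher (174 ± 17.404 to 245 ± 34.9 CPM, adjusted p = 0.0317), was named after its values were seen. Of 11 genes of the meiotic divisions and exit, 8 fell, 3 were not called and the median was -3.41. OSD1, an inhibitor of the anaphase-promoting complex, fell from 115 ± 8.29 to 10.03 ± 5.47 CPM, the meiotic cyclin gene TAM from 124 ± 19.1 to 22.6 ± 10.98 CPM, JASON from 212 ± 16.7 to 17.7 ± 10.7 CPM and the shugoshin gene SGO1 from 97.3 ± 3.75 to 29.8 ± 9.61 CPM. Adjusted over the list alone, 35 of the recombination genes were lower and 1 higher, and 9 of the division genes were lower. Camera gave an adjusted p of 6.19e-15 for the recombination list and 3.87e-05 for the division list, and both calls were lost with an estimated correlation (adjusted p = 0.391 and 0.459), while fry gave 0.00564 and 0.0067. In the same libraries the list of tapetum genes rose, as given below, and the mean of the recombination list relative to Ler was -1.71 in knu-2 replicate 1, -2.995 in replicate 2 and -2.85 in replicate 3. Without knu-2 replicate 1 the median of the division list was -4.05 and JASON was at -4.23. REC8 lost its call with DESeq2 size factors (adjusted p = 0.0779), with DESeq2 (0.0592) and without any 1 of the Ler replicates, knu-2 replicate 1 or knu-2 replicate 3 (0.0546 to 0.148).

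**Figure D2:**
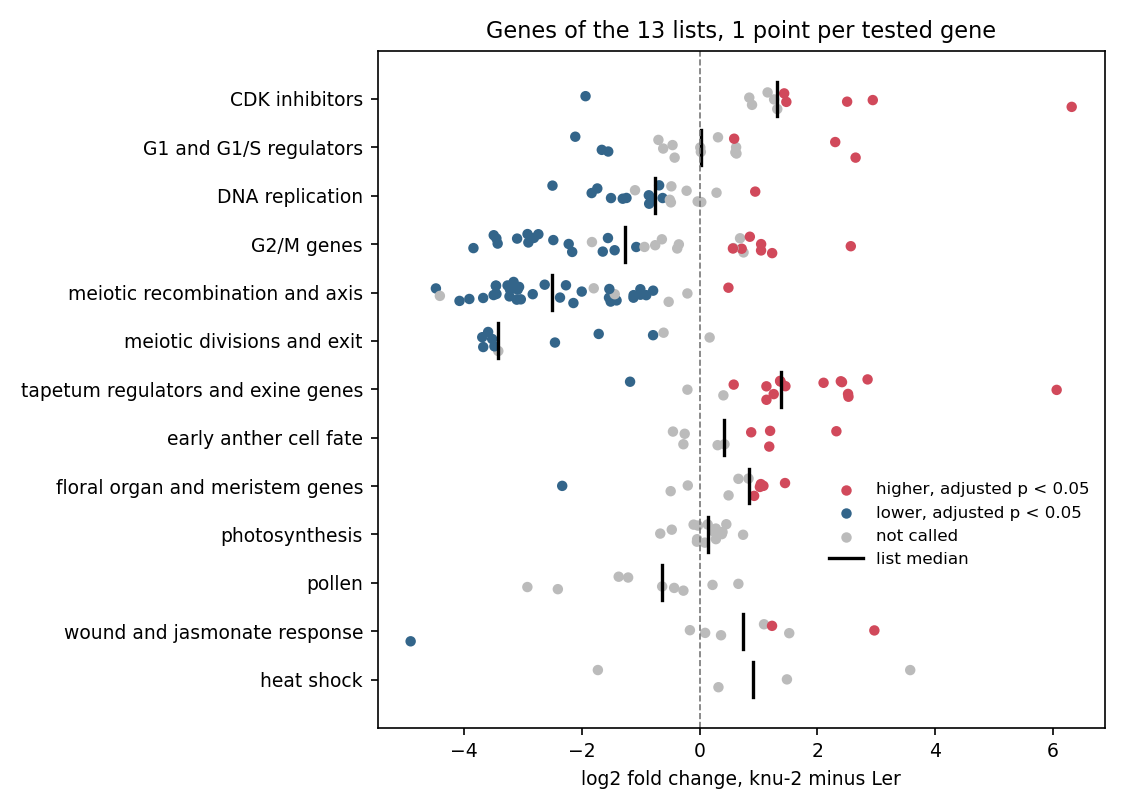
Log2 fold change of each tested gene in the 13 lists, knu-2 minus Ler, with a black bar at each list's median. Points are coloured by whether the gene was called higher, called lower or not called. The 2 meiotic lists have medians of -2.50 and -3.41 and the tapetum list has one of 1.37.

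Genes of the tapetum, the anther layer that feeds the meiocytes and makes pollen wall material, were higher in knu-2. Of 17 measured, 14 rose, 1 fell and 2 were not called, with a median log2 fold change of 1.37. The regulator AMS rose from 68.1 ± 11.8 to 359 ± 79.2 CPM (SD, n = 3 each), and 3 genes of sporopollenin synthesis rose with it: CYP704B1 from 26.6 ± 4.83 to 192 ± 34.6 CPM, ACOS5 from 38.9 ± 2.67 to 223 ± 52.3 CPM and TKPR1 from 91.0 ± 14.4 to 391 ± 74.8 CPM. DYT1, a regulator upstream of AMS that was named after its values were seen, fell from 6.97 ± 1.22 to 3.07 ± 0.927 CPM (adjusted p = 0.0339). Of 9 genes of early anther cell fate, 4 rose and 5 were not called, among them the receptor kinase genes SERK2 (log2 fold change 2.32, SE 0.22), BAM1 (1.198, SE 0.20) and RPK2 (1.18, SE 0.28) and the regulator SPL (0.88, SE 0.30), all 4 called higher. Of 11 floral organ and meristem genes, 5 rose, 1 fell and 5 were not called. SEP1 (1.45, SE 0.22), SEP3 (1.04, SE 0.21) and AP3 (1.02, SE 0.23), which specify floral organs, rose, and CLV1, a receptor of meristem signals, fell from 53.2 ± 2.19 to 10.6 ± 1.39 CPM. None of 15 photosynthesis genes was called by edgeR, at a list median of 0.14, and PSBP1, RBCS1B, LHCB1.2 and LHCA1 had log2 fold changes of 0.39, 0.74, -0.67 and 0.38. None of 9 pollen genes was called either, at a median of -0.63, and ANX1, PPME1, DUO1 and BCP1 had 0.66, -2.92, -2.40 and -1.21. In both lists 0 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Adjusted over the list alone, 14 tapetum genes were higher and 1 lower, 4 early anther genes were higher, 6 floral genes were higher and 1 lower, and none was called in the photosynthesis and pollen lists. Camera called the tapetum list (adjusted p = 2.41e-06, and 0.391 with an estimated correlation; fry 0.00393) and did not call the early anther (0.0809), floral (0.125), photosynthesis (0.836) and pollen (0.536) lists. The call of SPL was lost without Ler replicate 1 or 3 or knu-2 replicate 1 or 3 (adjusted p = 0.0693 to 0.12), and that of DYT1 without any 1 of the Ler replicates or knu-2 replicate 1 (0.0661 to 0.137) and with no scaling beyond library totals (0.113). Leaving out 1 knu-2 library gave a call to PSBP1 (0.0282 without replicate 1), to 3 photosynthesis genes that included LHCB1.2 (0.00243 without replicate 2), to PPME1 (0.0248 without replicate 3) and to DUO1 (0.0225 without replicate 2). With no scaling beyond library totals PSBP1 (0.0394) and ANX1 (0.0287) were called.

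**Figure D3:**
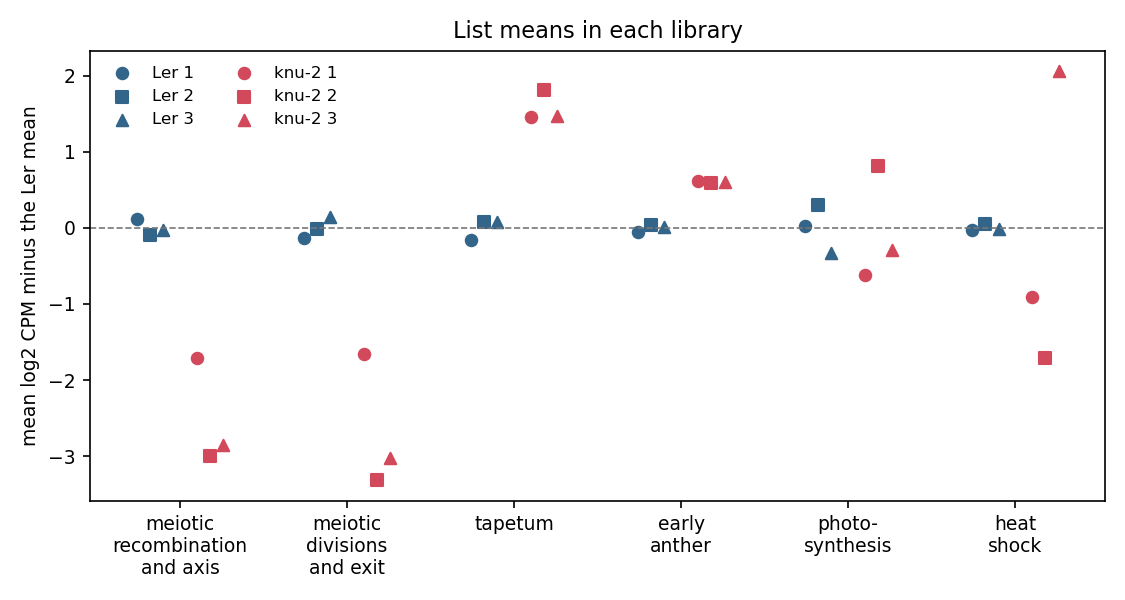
Mean log2 CPM of the members of 6 lists in each library, minus the mean of the Ler libraries, 1 point per library. The knu-2 libraries lie between -2.995 and -1.71 for meiotic recombination and axis genes and between 1.46 and 1.81 for tapetum genes, and knu-2 replicate 3 lies at 2.06 for heat shock genes.

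Cell cycle genes moved in both directions. Among 11 CDK inhibitor genes measured, 5 rose, 1 fell and 5 were not called, with a median log2 fold change of 1.32. KRP6 rose from 8.54 ± 0.484 to 65.6 ± 23.5 CPM (SD, n = 3 each), KRP7 from 21.5 ± 4.16 to 122 ± 6.36 CPM and SMR1 from 0.111 ± 0.146 to 9.78 ± 5.54 CPM, and KRP2 fell from 21.7 ± 3.78 to 5.67 ± 1.35 CPM. KRP3 and KRP4 (1.44, SE 0.31, named after its values were seen) were the other two that rose. SMR1 overlaps AT3G10527 on the opposite strand, and whether the counting used strand is not given in the sources used here. Of 16 G1 and G1/S regulators, 3 rose, 3 fell and 10 were not called. The D-type cyclin genes CYCD2;1 (2.65, SE 0.28) and CYCD4;1 (2.30, SE 0.30) rose, and the E2F transcription factor genes E2FC (-2.11, SE 0.25) and E2FB (-1.55, SE 0.19) fell. Of 20 DNA replication genes, 11 fell, 1 rose and 8 were not called, at a median of -0.75. The sliding clamp gene PCNA2 (-2.49, SE 0.25) and the helicase subunit genes MCM7 (-1.73, SE 0.27) and MCM2 (-0.85, SE 0.20) fell, and CDT1A, which licenses replication origins, rose (0.95, SE 0.17). Of 32 G2/M genes, 16 fell, 7 rose and 9 were not called, at a median of -1.26. The kinase gene CDKB2;1 fell from 332 ± 28.1 to 29.6 ± 7.93 CPM, and CDKB2;2 (-2.48, SE 0.23), the cyclin gene CYCA1;1 (-2.90, SE 0.22) and the Aurora kinase gene AUR3 (-2.22, SE 0.21) fell with it. In knu-2 replicates 1, 2 and 3 the list means lay -0.32, -1.28 and -0.97 from the Ler mean for replication and -0.73, -1.36 and -1.505 for G2/M genes. In the same libraries the tapetum list lay 1.46, 1.81 and 1.48 above it. Adjusted over the list alone, 6 CDK inhibitor genes were higher and 1 lower, 3 G1 and G1/S regulators were higher and 3 lower, 1 replication gene was higher and 12 lower, and 8 G2/M genes were higher and 19 lower. Camera gave an adjusted p of 0.0533 for CDK inhibitors, 0.836 for G1 and G1/S regulators, 0.00406 for DNA replication and 0.00464 for G2/M genes, and with an estimated correlation the adjusted p-values of the last pair were 0.669 and 0.55. The G1 and G1/S list had a median of 0.018 and a mean of 0.015 but a camera direction of lower. The CDK inhibitor list passed camera with DESeq2 size factors (adjusted p = 0.0401), with the filter at an average of 5 CPM (0.048) and without knu-2 replicate 3 (0.0394). Over its alternatives the adjusted p ranged from 0.00564, given by fry, to 0.391, given by camera with an estimated correlation. With no scaling beyond library totals 7 in place of 11 replication genes were lower and 2 in place of 1 higher. Without knu-2 replicate 1, 5 in place of 3 G1 and G1/S regulators were lower, and without Ler replicate 2 SMR1 was at 8.31.

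Of 8 wound and jasmonate response genes, 2 rose, 1 fell and 5 were not called (camera adjusted p = 0.412). The storage protein genes VSP2 (log2 fold change 2.97, SE 0.58) and VSP1 (1.23, SE 0.36) rose, AOS, which makes a jasmonate precursor, fell (-4.90, SE 1.25), and LOX2 was at 1.52 (SE 0.60) and not called. None of the 4 measured heat shock genes was called by edgeR (camera adjusted p = 0.836, with a median of 0.90 but a test direction of lower). Of these, 1, HSP90.1, had an unadjusted p under 0.05 and was called lower by DESeq2 (adjusted p = 0.0277) and limma-voom (0.00162). HSP101 was at 160 CPM and the heat shock factor gene HSFA2 at 24.7 CPM in knu-2 replicate 3, against at most 9.08 and 0.612 CPM in the other knu-2 libraries. HSP90.1 was at 604 ± 51.3 CPM in Ler and 183 ± 153 CPM in knu-2, and HSP17.4 at 16.4 ± 4.64 and 20.4 ± 11.5 CPM (SD, n = 3 each). Adjusted over the list alone, 2 wound genes were higher and 1 lower, and no heat shock gene was called. Without knu-2 replicate 3, HSP101 was lower in knu-2 (-1.47, adjusted p = 0.00374), as was HSP90.1 (-2.65, adjusted p = 0.000284), and LOX2 was called higher (1.80, adjusted p = 0.0475), as it was without Ler replicate 2 (2.17, adjusted p = 0.0159), with DESeq2 (0.00661), with limma-voom (0.0238) and with no scaling beyond library totals (0.031). VSP1 lost its call without Ler replicate 3 or knu-2 replicate 1 or 2 (adjusted p = 0.0507 to 0.0803), and VSP2 was at 2.17 without knu-2 replicate 2. AOS was at -4.30 without knu-2 replicate 3, had no count left in knu-2 without knu-2 replicate 1 and was not measured with the filter at an average of 5 CPM.

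Among the gene families found by keyword, camera called histone, kinesin and pentatricopeptide repeat genes toward lower levels in knu-2 and ribosomal protein and lipid transfer protein genes toward higher levels. All of these calls were lost with an estimated correlation (adjusted p = 0.708 for each). Of 40 histone genes, 31 fell, 3 rose and 6 were not called, at a median log2 fold change of -1.16. HTA6, an H2A gene, fell from 718 ± 128 to 109 ± 43.8 CPM (SD, n = 3 each) and the H3 gene AT4G40040 from 716 ± 49.5 to 282 ± 24.1 CPM. Of 27 genes described with the word kinesin, 18 fell, 1 rose and 8 were not called, at a median of -1.30. The 2 named members were AT2G21380, which fell (-2.19, SE 0.20), and ATK2, the 1 that rose (2.51, SE 0.20). Microtubule motor genes described without that word, such as HIK and TES, were not counted in this family. Of 285 pentatricopeptide repeat genes, whose products process organelle RNA, 104 fell, 26 rose and 155 were not called, at a median of -0.55, with LPA66 (-3.12, SE 0.24) and AT2G36240 (-2.21, SE 0.18) among the falls. Of 301 ribosomal protein genes, 138 rose, 29 fell and 134 were not called, at a median of 0.45, and AT5G39850 (2.77, SE 0.19) and AT1G25260 (2.42, SE 0.17) rose. Of 41 lipid transfer genes, 16 rose, 2 fell and 23 were not called, at a median of 0.66, and AT3G07450 (2.28, SE 0.21) and AT5G62065 (1.78, SE 0.18) rose. In the same knu-2 libraries the tapetum list lay 1.46, 1.81 and 1.48 above the Ler mean, and a change in the mix of cells was not tested apart from the family changes. No median of these families changed sign under another scaling. Camera's adjusted p-values over 14 families were 8.86e-08 for histones, 2.77e-05 for kinesins, 0.000517 for pentatricopeptide repeat genes, 1.72e-05 for ribosomal proteins and 0.00446 for lipid transfer proteins. The F-box, heat shock, pectin, WRKY, expansin, AGAMOUS-like, cytochrome P450, peroxidase and ubiquitin families had adjusted p-values of 0.254 to 0.845 and were not called by camera. With fry the WRKY family passed toward higher levels (adjusted p = 0.0439). The families that camera called had fry adjusted p-values of 0.0168 to 0.0439. With no scaling beyond library totals 41 pentatricopeptide repeat genes were higher and 15 ribosomal protein genes were lower, and 3 in place of 1 kinesin genes were higher (2 with the filter at an average of 5 CPM). Without Ler replicate 2, 15 pentatricopeptide repeat genes were higher, and 1 in place of 3 histone genes was higher without Ler replicate 1 or 2 or knu-2 replicate 1 or 2. For the lipid transfer genes 1 in place of 2 was lower without any 1 of the Ler replicates or knu-2 replicate 3, against 4 without knu-2 replicate 2.

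The genes around KNU were compared with the rest of the genome because a mutant line can carry linked variants. Within 5 Mb of KNU, 962 of 1896 tested genes were called (50.7%), against 7880 of 16432 elsewhere (48.0%). The odds ratio was 1.12 (95% confidence interval 1.02 to 1.23, two-sided Fisher's exact p = 0.0225, adjusted over 3 windows 0.0376). In 121 windows of 1 Mb, 2 windows on chromosome 2 passed after adjustment, and both held fewer called genes than the genome, 71 of 215 and 3 of 23.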

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

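Of 81 named genes, 77 had the same sign under every alternative they were measured in, and 15 gained or lost a call or reversed in at least 1. The other 4 were HSP101, HSFA2, HSP17.4 and LHCA1, none of them called with all libraries. HSP101 was called in the opposite direction, at -1.47 without knu-2 replicate 3, the library that held most of its knu-2 counts, within a range of -1.47 to 2.02 over the libraries left out (2.02 without knu-2 replicate 2). KNU was lower under every alternative, with log2 fold changes of -3.69 to -2.85. KRP1 gained a call at 1.501 with no scaling beyond library totals, which shifts all genes upward, and at 1.26 with the filter at an average of 5 CPM, and leaving out each library gave 0.84 to 1.39. KRP3 was at 1.14 to 1.79 when each library was left out, and lost its call in 2 of these cases. For the losses with fewer samples, fewer samples are part of the setting, and otherwise the cause was not tested. Leaving out each library gave 3346 to 4062 higher and 3889 to 4742 lower genes. The CDK inhibitor list passed at medians of 1.27 with DESeq2 size factors, 1.56 with the filter at an average of 5 CPM and 1.32 with fry. Leaving out each library gave medians of 1.09 to 1.45. With the fold changes of the DESeq2 Wald test its median was 1.08. The list test there was the same camera test as with DESeq2 size factors (adjusted p = 0.0401), so it is not a further alternative. The early anther list passed with fry at a median of 0.42. With an estimated correlation no list or family was called, which ended the camera calls of DNA replication (-0.75, also lost with fry), G2/M (-1.26), meiotic recombination and axis (-2.50), meiotic divisions (-3.41) and tapetum genes (1.37), and of ribosomal proteins (0.45), histones (-1.16), kinesins (-1.30), lipid transfer proteins (0.66) and pentatricopeptide repeat genes (-0.55). The median of the meiotic recombination and axis list was -2.18 with no scaling beyond library totals. DESeq2 called 4120 genes higher and 4985 lower, limma-voom 4302 and 4780, and thresholds of 1 on the log2 scale and of 0.01 on the adjusted p left 2905 and 3053 and 2951 and 3502. The samples share only a replicate number: deviations from the genotype means correlated at -0.121, 0.103 and 0.0523 for numbers 1, 2 and 3, and Ler replicate 1 correlated best with knu-2 replicate 3 (0.130). With a replicate block, 4284 genes were higher and 4562 lower, of which 4125 and 4361 were called without it, and the CDK inhibitor list passed at a median of 1.16. With this block AT3G18180 (adjusted p = 0.0767), AT2G34580 (0.0878), AT1G65165 (0.186) and DYT1 (0.0527) were not called, and LOX2 (0.00422) and LHCB1.2 (0.0101) were. On simulated libraries with 1 dispersion for all genes (0.117), 6% of 2-fold changes were found. There 100 of 18422 genes were changed 2-fold and 100 were changed 4-fold, whereas 48.1% of the tested genes were called here. The adjusted p depends on that share, so the 6% does not carry over to these data. RBR1, for example, was called here at a log2 fold change of 0.59 (edgeR adjusted p = 0.00743). A count of 0 in a library allows a level of up to 0.119 to 0.166 scaled CPM (3 counts), so a gene with no count is not shown to be absent.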

Other observations

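The tests of description words, of the meiotic gene pattern, of genes with no count in Ler and of phosphate genes were chosen after the results they concern were seen, and the counts over other splits of the samples were planned. Among 496 words in the reference descriptions of tested genes, those of the exocyst, the complex that tethers secretory vesicles at the plasma membrane, stood out among the falls. Of 30 exocyst genes, 20 were lower and 1 was higher in knu-2 (one-sided Fisher's exact test against all tested genes, adjusted p = 0.000238, treating genes as independent). SEC3A was at 562 ± 34.1 CPM in Ler and 142.5 ± 34.5 CPM in knu-2 (SD, n = 3 each), SEC5B at 402 ± 31.4 and 93.7 ± 28.02 CPM and EXO84B at 208 ± 2.86 and 67.2 ± 5.47 CPM, while EXO70G1 was the 1 that was higher, at 22.03 ± 1.72 and 45.5 ± 5.96 CPM. Of 23 genes described with the word tubulin, 13 were lower, 1 was higher (AT3G57890, log2 fold change 0.74) and 9 were not called (adjusted p = 0.0453), with TUA6 at 2251 ± 206 and 769 ± 244 CPM and TUB7 at 895 ± 75.6 and 112 ± 20.22 CPM. Of the genes described with the word motor, some of which are in the kinesin family above, 16 were lower and 0 higher. The others, HIK among them, were not called. The 16 include AT2G42510 (log2 fold change -3.18), which is described as a survival motor neuron interacting protein and not as a microtubule motor. The median log2 fold change of all genes with the word motor was -2.01, against -1.36 for the exocyst and -0.69 for the tubulin genes. With no scaling beyond library totals, 17 exocyst, 12 tubulin and 15 motor genes were lower and 3, 4 and 2 were higher. The tapetum list rose in the same libraries (14 of 17 genes higher), and a change in the mix of cells was not tested apart from these falls.

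Peroxins, the proteins that build peroxisomes, moved the other way. Of 15 peroxin genes, 11 were higher and 1 was lower in knu-2 (one-sided Fisher's exact test, adjusted p = 0.00595), and the same numbers were called with no scaling beyond library totals. PEX19-2 was at 2.76 ± 0.499 CPM in Ler and 29.2 ± 5.88 CPM in knu-2, PEX19-1 at 11.6 ± 1.83 and 45.7 ± 4.22 CPM and PEX13 at 33.1 ± 1.81 and 70.5 ± 11.5 CPM (SD, n = 3 each), and PEX11A was the 1 that was lower, at 49.8 ± 5.61 and 29.5 ± 2.88 CPM. The tapetum list rose in the same libraries, at a median log2 fold change of 1.37, and other cells in the collections were not tested as a source of this rise.

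The fall of meiotic recombination and axis genes could come from the makeup of the cells pressed out of the anthers, since no sort is named in the labels. An even dilution of meiocyte RNA by the other anther cells would raise their lists alike. The tapetum mean minus the photosynthesis mean was 2.08, 1.00 and 1.77 in knu-2 and -0.18, -0.23 and 0.41 in Ler. The difference was 1.62 (SD 0.55 and 0.35, exact permutation p = 0.1, the smallest possible), so these 2 lists did not rise alike. In knu-2 replicates 1 to 3 the early anther list lay 0.62, 0.60 and 0.61 above the Ler mean, and the floral list 0.55, 0.49 and 0.08. The test was chosen after the values were seen and used only the tapetum and photosynthesis lists. It therefore does not decide on an even dilution. More tapetal RNA in the knu-2 collections cannot be told apart from a change within meiocytes: knu-2 replicate 1, with the smallest fall of the meiotic list, had a tapetum mean 0.014 below (-0.014) replicate 3 and 0.35 below (-0.35) replicate 2, 3 libraries are too few to relate the lists, and no library of tapetal cells alone was analysed here. Of 23 listed tapetum genes, 17 passed the filter, which was applied to both genotypes together. The most abundant, KNS4 and A9, were at 279 and 125 CPM in Ler and at 719 and 670 CPM in knu-2, whereas MS1, MS2 and CYP703A2 had no count in any library. A different average anther stage stays open as well, with the division list -0.92 from the recombination list (permutation over genes taken as independent, p = 0.312), as does an effect of the genotype on meiocytes, which was not tested apart from these.

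Of genes with no count in Ler and at least 2 CPM in each knu-2 library there were 9, on 4 chromosomes, and in the reverse direction there were 2, ABCG23 and ATSAC1B. The limit of 2 CPM was applied without the TMM factors, which differ between the genotypes, so it is not the same scaled level in both directions. A chromosome segment linked to KNU might carry such differences, but 1 of the 9, AT5G03545, lies within 5 Mb of KNU, which argues against a linked segment as the source of the others. ABCG23 lies within 5 Mb of KNU too, so a linked segment stays open for ABCG23 and AT5G03545. A genetic background of knu-2 that differs from Ler across the genome could give genes that Ler lacks, but the counts of 9 and 2 leave it open. The exact two-sided binomial p was 0.0654, with genes taken as independent, although AT1G36920 and AT1G36922 are neighbours. PAP25 and AT5G03545, 2 of the 9, are also among the phosphate genes below. The history of the line is not given in the sources used here, and a change of gene activity that depends on KNU was not tested apart from such a background.

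PEPC1 and 3 more genes known to be induced by phosphate starvation, PAP25, MGD3 and AT5G03545, were noticed among the rises, and a candidate explanation is a phosphate starvation type response in the knu-2 libraries. A list of 19 further genes was tested, of which 14 were measured, with a median log2 fold change of 1.03 (camera p = 0.0470, p = 0.102 with an estimated correlation and fry p = 0.000118). SPX1, SQD1, PS2, PAP17, RNS1 and SRG3 were higher, with PS2 at 3.71 ± 0.801 CPM in Ler and 42.8 ± 3.00 CPM in knu-2 (SD, n = 3 each), SPX2 was lower, and 7 were not called by edgeR. IPS1, SPX3 and PHT1;1 had no count in any library. The camera p-value was under 0.05 at the preset correlation and not at the estimated one, so camera does not decide the question. The rises are in keeping with part of such a response. The growth conditions were not compared here, and a change in the mix of cells was not tested against such a response.

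The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The split by genotype called 8856 genes and the highest of the others called 0 (with edgeR, and 293 at an unadjusted p under 0.05), so that 1 split gave as many genes. For the gene lists, camera with the preset correlation called 5 lists in the split by genotype and up to 8 in the others. Counting the split by genotype itself, 5 of the 10 splits gave as many lists. Every other split has unequal numbers of Ler and knu-2 libraries in each group. The genotype difference therefore adds to the spread within its groups, and part of it stays between them. Neither count thus measures what chance alone would give.

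The mean of the photosynthesis list relative to Ler was 0.81 in knu-2 replicate 2 and -0.62 in knu-2 replicate 1. The mean of the pollen list was -3.42 in knu-2 replicate 1, against -0.80 and -0.19 in replicates 2 and 3.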
